A study of Homo sapiens with 6 samples.

How the data were processed

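ChIP-seq with an antibody to ARNT was made in BeWo cells held at 1% oxygen for 24 h, with 3 ARNT ChIP libraries and 3 input libraries. Per the labels, chromatin was fixed with formaldehyde, sonicated and immunoprecipitated, and libraries were built with a ligation kit. The submitters' processing notes name BWA 0.7.17, MACS2, deepTools 3.3.2 and the genome build hg38; filters, the use of the input as control and the cutoff were not given in the sources used here. The authors called peaks in each ChIP library separately and deposited a list per replicate in narrowPeak layout. In these lists the deposited fold enrichment is a ratio over the peak caller's local background at the summit, and the deposited significance values are the −log10 p and −log10 q of each peak. The lowest −log10 q was 1.34, 1.36 and 1.30 in replicates 1, 2 and 3. The deposited score in these lists was 10 times the −log10 q rounded down in all peaks (100.0%). The authors' remaining value is the summit offset in bp.

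The combined list has no header and no stated method. The authors' summed value in it equalled the sum of the folds of the strongest overlapping replicate peaks in 1769 of 1810 regions (97.7%, within 0.001). The authors' score in it equalled 125 times −log2 of the p-value, capped at 1000, in all regions (100.0%). The authors' p-value reached 0.148 at most. A further value in the authors' list, larger and in the same order, was at most 0.05 in 131 regions and had a median of 0.550; it resembles an adjusted p-value but is not named as one. The list holds 12 pairs of touching regions.

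Read totals were not given in the sources used here. Depth and its effect on the number of peaks in a library are therefore unknown, and the Wilson 95% intervals over peaks cover counting error only. Input libraries entered no test. Regions are given in hg38, counted from 1, and gene positions come from a RefSeq table of GRCh38.p14, the same build, with 20037 protein-coding genes on assembled chromosomes. Peaks on other contigs (2, 11 and 12 in replicates 1, 2 and 3) were left out of the tests.

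Peaks overlapped when they shared at least 1 bp. Pairs of replicates were compared with 1000 random placements of the smaller list that kept widths and chromosomes and spanned the annotated gene range of each chromosome. Distances were measured from region midpoints to either end of the nearest protein-coding gene. The share within 1 kb was compared with 1000 random placements, and the shares by location with 20 placements. A gene was bound when a combined-list midpoint lay within 5 kb of either end. Each gene list was compared with 10000 random lists of the same size, matched on the decile of the number of protein-coding genes within 500 kb, by a one-sided permutation test with Benjamini-Hochberg adjustment over the 24 lists. An adjusted value under 0.05 counted as past the test. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

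The test was tested on simulated data over the 20037 genes, with 200 lists of 25 genes at each effect size. At an unadjusted 0.05 it called 2.0% of lists with no excess, 19.0% of those bound at a ratio of 2, 77.0% at 4 and 100.0% at 8. A list with a small excess can therefore be missed.

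Choices were fixed before the data were examined, with exceptions. No genome sequence was used here, so the share of regions with the HIF core sequence at the summit, its relation to the number of replicates, the panel of 24 motifs and the count of short sequences were not run. Matching on promoter GC content was replaced by matching on local gene density for the same reason. Random placement could not avoid gaps in the assembly, again for lack of the sequence. The gene table has no strand, so distances to transcription starts were replaced by distances to gene ends. The combined list has no summits, so midpoints were used.

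Genes are named by a rule fixed before the data were examined. It takes the 20 combined-list regions with the highest summed fold, each by its nearest protein-coding gene, up to 4 bound members with the highest summed fold of each list past the test, and 20 genes chosen for HIF, trophoblast and aryl hydrocarbon receptor biology. Other bound members of small lists, and all genes named only in the closing section, were chosen after their values were seen. The 24 gene lists hold 568 entries and 538 different symbols, all of which matched the gene table. They cover glycolysis and glucose or lactate transport; oxygen sensing and HIF feedback; hypoxia-induced genes; angiogenesis and placental vascular factors; JmjC histone demethylases; histone deacetylases and acetyltransferases. They also cover collagen modification and matrix, mitophagy and autophagy, oxidative phosphorylation and TCA cycle, acid-base transport, aryl hydrocarbon receptor targets, circadian clock, syncytiotrophoblast and fusion, cytotrophoblast and trophoblast stem cell, and extravillous trophoblast. The remaining lists are iron and heme handling, lipid storage and fatty acid handling, cell cycle arrest and mTOR restraint, unfolded protein and stress response, cytosolic ribosomal proteins, neuronal, hepatocyte, skeletal and cardiac muscle, and immune cell.

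Alternatives were the overlap that counts as shared, stronger peaks only, other region sets, other distances, no matching, Fisher's exact test, and each replicate left out in turn. Added after seeing the data were placement beside gene ends, the summit in place of the midpoint, a background of genes with a peak in any replicate, lists without hypoxia-induced genes, regions with the authors' further value of at most 0.05, and gene bodies. The patterns weighed in the closing section changed while the work went on. A pattern of strong regions lying away from gene ends was dropped because it was not present. The 50 kb pattern at cytotrophoblast genes was taken up after 1 of 24 lists was seen to pass in 2 of 15 alternative settings (50 kb and gene bodies), and it took the place of the regions left out of the combined list; the tests already run on those are still reported.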

Results

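The series mapped ARNT on the chromatin of BeWo cells, a trophoblast line derived from human choriocarcinoma, after 24 h at 1% oxygen. ARNT is the partner that the alpha subunits of the hypoxia-inducible factors (HIF) and the aryl hydrocarbon receptor need in order to bind DNA. The samples fell into 3 ARNT ChIP libraries and 3 input libraries, and every library came from cells at 1% oxygen, so no region could be compared between oxygen levels. Each ChIP library had its own peak list, with 2644 peaks in replicate 1, 9677 in replicate 2 and 6916 in replicate 3, and the authors also gave a combined list of 1812 regions. The input libraries were not used here. The fold enrichment of each peak is the authors' own value, which the combined list adds up over the replicates as a summed fold. In 1769 of 1810 regions this was the sum of the strongest overlapping peak of each replicate; in the others, those at GAPDH, BHLHE40, BHLHE41, BNIP3L and KDM4C among them, it differed from that sum. Read totals were not given in the sources used here, so the depth behind each peak is unknown. Nothing in the labels says that the replicates were separate cultures, so agreement between them may be technical.

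The strongest 20 ARNT regions were found in every replicate, and 13 of them lay over 5 kb from a protein-coding gene end, as did 56.6% of all regions. The region with the highest summed fold, 214, lay inside SLC8A2, a sodium-calcium exchanger gene (chr19:47447488-47448446), with a fold of 33.1 in replicate 1, 106 in replicate 2 and 74.99 in replicate 3. Among the strongest 20 regions, 7 lay within 5 kb of a protein-coding gene end and 7 lay over 50 kb from any. Those near a gene end included PTTG1IP (summed fold 167, 304 bp from the end), HILPDA, which encodes a lipid droplet protein (156, 155 bp), and ANKRD37, a small ankyrin-repeat gene known as a HIF target (148, 347 bp). The midpoint of the region counted for ANKRD37 lay inside LRP2BP, another protein-coding gene. A region of 142 lay inside PFKFB4, a regulator of glycolytic flux (chr3:48556818-48557640), 5907 bp from the nearer end of that gene and 4489 bp from an end of UCN2.

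Several of the strongest regions were distal. A region of summed fold 170 (chr1:43005005-43008008) lay 47639 bp from SLC2A1, the gene of the glucose transporter GLUT1, outside annotated genes. Its strongest peaks had folds of 12.7, 80.3 and 32.9 in replicates 1, 2 and 3, which add up to 126 and would place it at rank 30. Another lay inside EGFR, the epidermal growth factor receptor gene, and its antisense gene EGFR-AS1 (chr7:55180901-55181966, summed fold 166). RBPJ, the DNA-binding effector of Notch signalling, held a region of 180 (chr4:26318798-26319876). GSE1 held a region of 179 (chr16:85514520-85515865) whose nearest gene end was that of GINS2, 161005 bp away. The remaining regions of the 20 were nearest to ODF1 (195), ARRDC3 (188), JAM3 (174), TBC1D22A (170, at the long non-coding gene EPIC1), LOC124901355 (165), PARN, RNF126 (157), PPP1R3E (153), HNRNPLL (146) and FAM178B (138). PARN was nearest to a pair of touching regions that shared the summed fold 164.716 over LINC02130, although the strongest peaks over each added up to 148 and 89.1, so 1 locus took 2 of the 20 places. Across the 20 regions the fold in replicate 1 ran from 5.10 to 33.1, below that of both other replicates in each region.

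**Figure D1:**
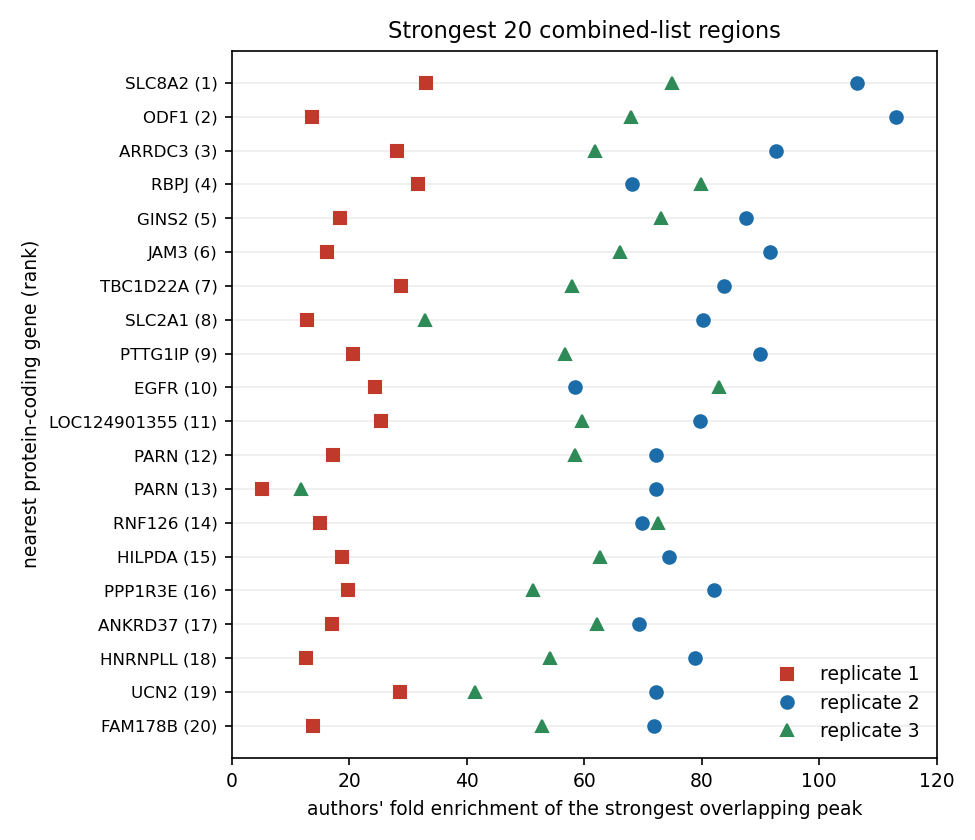
Points give the authors' fold enrichment (x axis, ratio) of the strongest peak of each ARNT ChIP replicate over each of the 20 combined-list regions with the highest summed fold (y axis, nearest protein-coding gene and rank). Replicate 1 lies lowest in every region, at 33.1 in the region inside SLC8A2 against 106 in replicate 2 and 74.99 in replicate 3.

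How far the 3 ChIP libraries agree was asked by overlapping their peaks. Merging the lists gave 10684 regions on assembled chromosomes, of which 2415 (22.6%) had a peak in all 3 replicates, 3620 (33.9%) in 2 and 4649 (43.5%) in 1. PDK1, LDHA, ADM, BNIP3, KDM3A, EGLN1 and VEGFA had a peak within 5 kb in all 3 libraries. Replicate 1 added few regions of its own, 43, against 3639 found in replicate 2 alone, and 3460 were shared by replicates 2 and 3 without replicate 1. Of the smaller list in each pair, 97.8% of peaks overlapped between replicates 1 and 2 (2583 of 2642, Wilson 95% interval 97.1 to 98.3), 92.5% between 1 and 3 (2444 of 2642, 91.4 to 93.4) and 85.7% between 2 and 3 (5920 of 6904, 84.9 to 86.6). Random placement of the peaks on the same chromosomes gave 0.42%, 0.28% and 0.40% (one-sided permutation p = 0.001 for each pair, the smallest these permutations can give). Placement beside gene ends, chosen after seeing the data, gave 2.19%, 1.34% and 1.87%. Across the 2415 regions found in all 3 replicates, which are not independent of one another, fold enrichment had a Spearman correlation of 0.647 between replicates 1 and 2, 0.615 between 1 and 3 and 0.808 between 2 and 3.

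Strong peaks were shared more often than weak ones. Of the replicate 2 peaks in the highest 25% by fold (median 16.0), 72.4% overlapped a replicate 1 peak and 97.4% a replicate 3 peak. In the lowest 25% (median 4.29) the shares were 3.68% and 24.5%. Replicate 1 decided the count of shared regions, since 5875 regions were found in both other replicates when it was left out. With the 1000 peaks of each list that had the highest −log10 q, 657 regions were found in all 3.

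**Figure D2:**
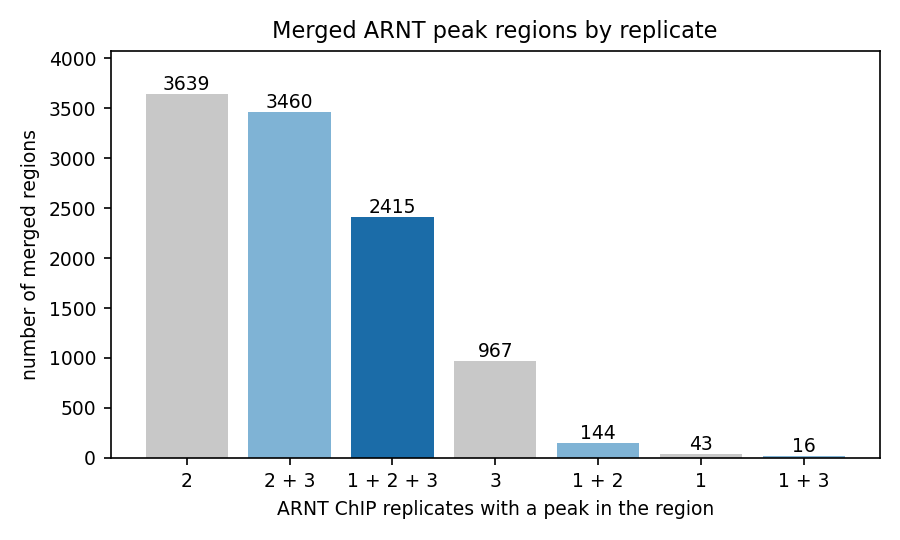
Bars give the number of merged regions (y axis) by the set of ARNT ChIP replicates with a peak in the region (x axis). Regions of replicate 2 alone numbered 3639, those of replicates 2 and 3 numbered 3460, and those of all 3 numbered 2415.

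Nearly all of the combined list, the regions at PDK1, ADM and HILPDA included, had a peak in all 3 libraries. Of its 1810 regions on assembled chromosomes, 1746 (96.5%, 95.5 to 97.2) overlapped a peak of every replicate, and these covered 72.3% of the 2415 regions found in all 3 lists. Among the 669 regions that were left out was the one at VEGFA, the gene of the vascular endothelial growth factor A, whose folds were 4.30, 8.46 and 7.94 in replicates 1, 2 and 3 (chr6:43769444-43770132, 423 bp from the gene). The regions kept had a median summed fold of 39.3, against 20.4 for those left out. The authors' p-value was at most 0.05 in 1107 regions, those at PDK1 and ANKRD37 among them.

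Binding was concentrated at gene ends relative to chance, with most regions nevertheless elsewhere. EGLN1, which encodes the oxygen-sensing prolyl hydroxylase PHD2, had a region 20 bp from its end (summed fold 68.0), LDHA, the gene of lactate dehydrogenase A, had one 103 bp away (78.3), and BNIP3, a mitophagy receptor gene, had one 163 bp away (113). Overall 519 of the 1810 regions (28.7%, 26.6 to 30.8) had their midpoint within 1 kb of a protein-coding gene end, against 2.97% of regions placed at random (ratio 9.66, one-sided permutation p = 0.001, the smallest these permutations can give). The gene table gave no strand, so a gene end here is either end of the gene and not the start of transcription alone. A further 33.5% lay inside protein-coding genes (41.7% at random), 10.3% inside other annotated genes (13.3%) and 27.5% outside annotated genes (42.3%). The median distance to a protein-coding gene end was 8301 bp, against 54045 bp at random, and 56.6% of regions lay over 5 kb away. Random placement did not avoid gaps in the assembly, where no peak can lie. Its shares near gene ends may therefore be too low and its distances too long.

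**Figure D3:**
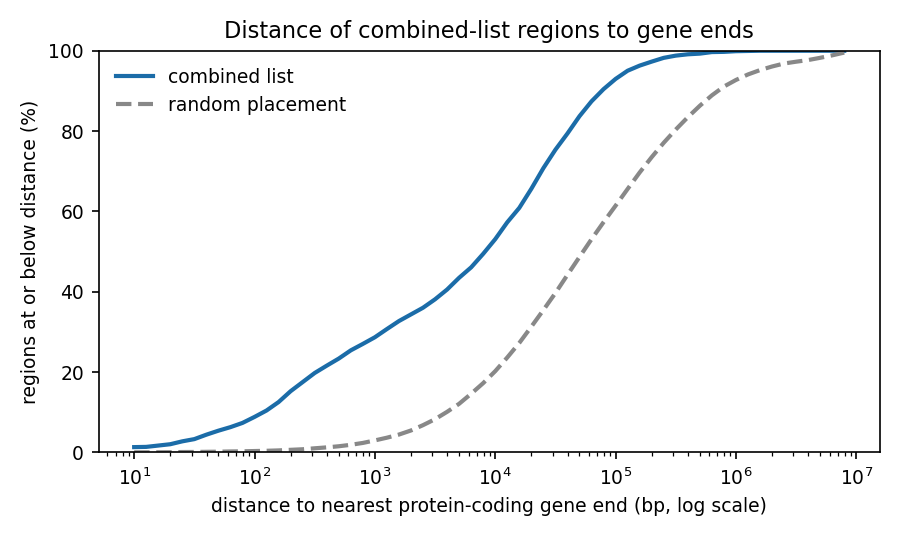
Lines give the share of regions (y axis, percent) at or below a distance to the nearest protein-coding gene end (x axis, bp, log scale) for the combined list (solid) and for random placement on the same chromosomes (dashed). At 1 kb the combined list stood at 28.7%; its median distance was 8301 bp against 54045 bp for random placement.

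Glycolytic genes were among the most frequently bound groups. A gene was called bound when a combined-list region had its midpoint within 5 kb of either gene end, which held for 975 of 20037 protein-coding genes (4.87%). Of the 25 genes of glycolysis and of glucose or lactate transport, 16 were bound, against 1.29 in random lists matched on local gene density (adjusted permutation p = 0.00080). ENO1, the gene of enolase 1, had the highest summed fold of the list (129, chr1:8878285-8879578), followed by PDK1, a mitochondrial kinase that inhibits pyruvate dehydrogenase (129, chr2:172555466-172556750), GAPDH (118, chr12:6532324-6534966) and PGK1 (116, chrX:78103626-78104474), which both act in lower glycolysis. At PDK1 the fold was 18.4 in replicate 1, 64.6 in replicate 2 and 45.6 in replicate 3. SLC2A1 was bound 3960 bp from its end with a summed fold of 58.2, below that of the distal region 47639 bp away. A weaker region found in all 3 replicates lay 141 bp from the gene (chr1:42958735-42959283, folds adding up to 17.9) and was not in the combined list.

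Genes induced by hypoxia in many cell types had 24 of 36 members bound, against 1.69 expected (adjusted permutation p = 0.00080). HILPDA (chr7:128455301-128456145) and ANKRD37 (chr4:185395965-185397023) led this list, followed by PDK1 and by ADM, the gene of the vasodilator peptide adrenomedullin (123, chr11:10307357-10308514). The folds at HILPDA were 18.8, 74.4 and 62.6 in replicates 1, 2 and 3. Genes of oxygen sensing and HIF feedback had 5 of 16 members bound (0.73 expected, adjusted permutation p = 0.0018), namely ANKRD37, the transcriptional repressors BHLHE40 (115) and BHLHE41 (108, with strongest peaks that add up to 75.2), EGLN1, and SIAH2, a ubiquitin ligase gene (48.1). The authors' p-value of the region at BHLHE41 was 0.143, near the highest in the combined list, 0.148. The list of JmjC histone demethylases, oxygen-dependent enzymes most of which remove histone methylation, had 9 of 21 bound (1.01 expected, adjusted permutation p = 0.00080). JMJD6 and RIOX2, which are not established as histone demethylases, were among the 9. KDM5B (99.4), KDM3A (98.3), KDM4B (86.3) and KDM6B (76.2) were the strongest of them. The region counted for KDM5B lay 3182 bp from that gene and 1365 bp from an end of another protein-coding gene. The glycolysis and demethylase lists passed the test under all 15 alternative settings, oxygen sensing under 14, and the hypoxia-induced list under the 14 that could change it, since removing hypoxia-induced genes from the other lists left this list as it was.

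A further 5 lists passed, with 4 or 5 bound genes each. The collagen modification and matrix list had 5 of 22 bound (1.10 expected, adjusted permutation p = 0.0204), all of them enzymes that hydroxylate collagen or a subunit of one: PLOD2 (100.01), P4HA2 (87.6), P4HB (69.9), P4HA1 (68.3) and PLOD1 (43.1). The list of cell cycle arrest and mTOR restraint had 5 of 19 (0.879 expected, adjusted permutation p = 0.0067), led by DDIT4, an inhibitor of mTOR signalling (59.4), CCNG2 (49.5), CCNG1 (37.7) and CDKN1B (32.7). The region counted for CDKN1B lay 3047 bp from that gene and 501 bp from an end of another protein-coding gene. Mitophagy and autophagy had 4 of 20 bound (0.975 expected, adjusted permutation p = 0.0447), namely BNIP3, BNIP3L (85.1), MAP1LC3B (56.2) and ATG9A (48.7). The circadian clock list also had 4 of 21 (0.989 expected, adjusted permutation p = 0.0447), namely BHLHE40, BHLHE41, CIART (48.0) and PER1 (38.2). Lipid storage and fatty acid handling had 4 of 22 (1.07 expected, adjusted permutation p = 0.0496), namely HILPDA, PLIN2, which coats lipid droplets (74.6), LPIN1 (72.8) and SCD (47.5). These 5 lists share members with the hypoxia-induced list, and without the shared genes none passed (adjusted permutation p from 0.0619 for the clock to 0.443 for mitophagy), although the clock kept its 4 bound genes and its adjusted value moved with the other lists. With only genes that had a peak in at least 1 replicate as background, oxygen sensing also fell short (adjusted p = 0.139, one-sided Fisher exact test). Both settings were chosen after seeing the data. Among planned settings, cell cycle arrest fell short with the stronger 50% of the combined list (2 bound, adjusted permutation p = 0.170). The clock fell short with regions within 50 kb (6 bound, adjusted permutation p = 0.166). Each list passed in the setting where the other fell short (0.0038 for cell cycle arrest, 0.0368 for the clock). Collagen (6 bound, adjusted permutation p = 0.256) and lipid handling (5 bound, 0.398) also fell short with regions within 50 kb, and mitophagy passed (8 bound, 0.0312). With regions found in both other replicates, collagen fell short without replicate 1 (adjusted permutation p = 0.0689), mitophagy without replicate 1 (0.234) or 2 (0.0973), and lipid handling without any of the 3 (0.0689 to 0.120). With no replicate left out, mitophagy and lipid handling also fell short with regions of all 3 replicates (adjusted permutation p = 0.0957 and 0.109). Regions of at least 2 replicates gave 0.113 and 0.0766. Collagen, the clock and cell cycle arrest passed in both of these settings.

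**Figure D4:**
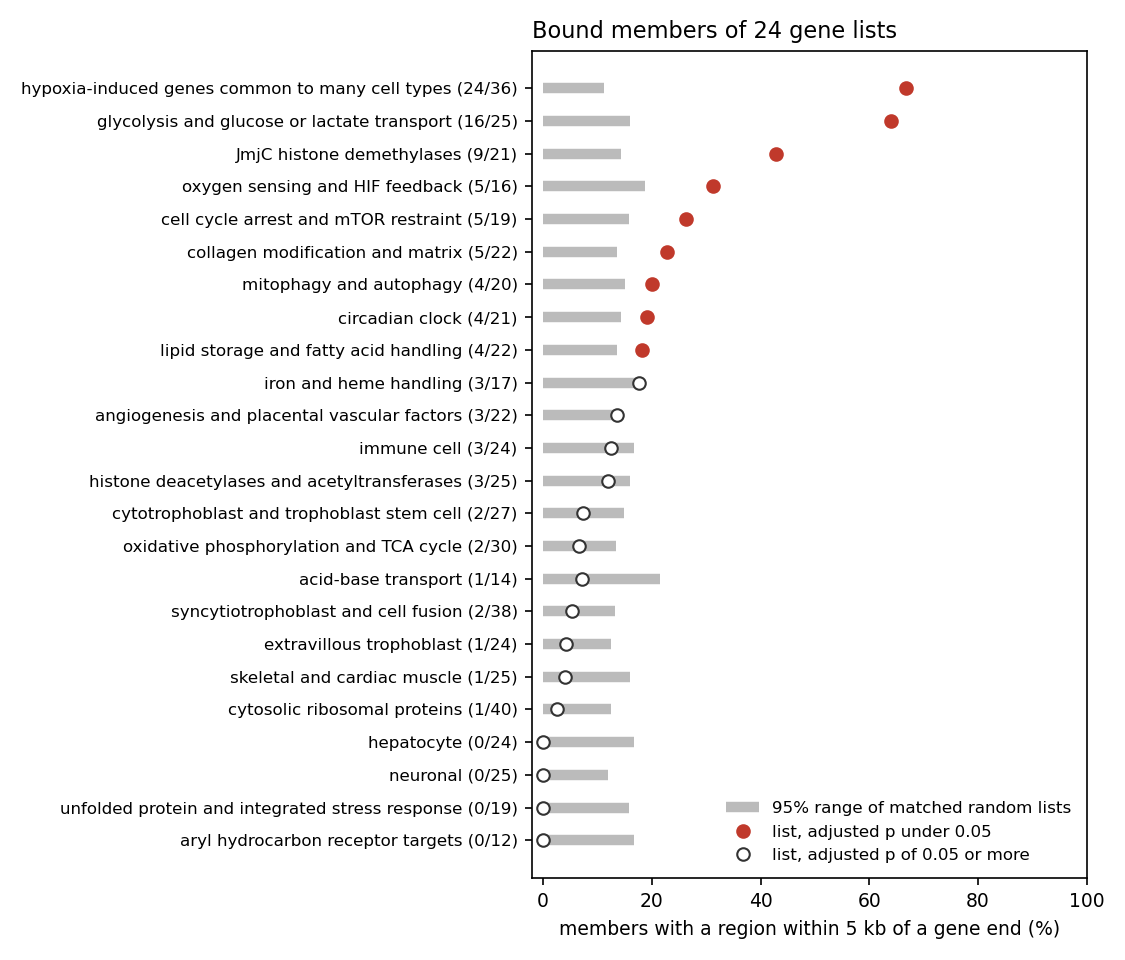
Circles give the share of each gene list's members (x axis, percent) with a combined-list region within 5 kb of a gene end, and grey bars the 95% range of 10000 random lists matched on local gene density. Filled circles mark the 9 lists with an adjusted permutation p under 0.05, led by the hypoxia-induced (24 of 36) and glycolysis (16 of 25) lists.

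Trophoblast identity genes were not bound beyond chance within 5 kb. Of the syncytiotrophoblast and fusion genes, 2 of 38 were bound, OVOL1 and CSH2 (2.03 expected, adjusted permutation p = 0.864). The cytotrophoblast and stem cell list had 2 of 27, LRP2 and ARID3A (1.23 expected, adjusted permutation p = 0.600), and the extravillous list 1 of 24, PLAC8 (1.07 expected, adjusted permutation p = 0.892). The cytotrophoblast list passed with regions within 50 kb (13 bound, 4.18 expected, adjusted permutation p = 0.00080) and with gene bodies included, a setting chosen after seeing the data (7 bound, 1.98 expected, adjusted permutation p = 0.0147). Angiogenic and placental vascular factors had 3 of 22 (1.00 expected, adjusted permutation p = 0.161), ENG (130), ADM and ANGPTL4 (59.1). Iron and heme handling had 3 of 17, CP, TFRC and SLC11A2 (0.848 expected, adjusted permutation p = 0.118). With regions found in both other replicates, iron handling passed without replicate 1 (7 bound, adjusted permutation p = 0.0252), 2 (5 bound, 0.0144) or 3 (5 bound, 0.0175), and the vascular list without replicate 1 (8 bound, 0.0176). The vascular list also passed with regions of at least 2 replicates (8 bound, adjusted permutation p = 0.0168), the stronger 50% of the combined list (3 bound, 0.0368) and regions with a further authors' value of at most 0.05 (2 bound, 0.0176), and iron handling with regions of at least 2 (7 bound, 0.0253) or all 3 replicates (5 bound, 0.0144). No aryl hydrocarbon receptor target was bound of 12 (0.551 expected), and none of 19 genes of the unfolded protein and stress response (0.987 expected), with an adjusted permutation p of 1 for each. Deacetylases and acetyltransferases had 3 of 25, HDAC3, KAT6B and KAT8 (1.26 expected, adjusted permutation p = 0.252). Oxidative phosphorylation and the TCA cycle had 2 of 30, NDUFB8 and ATP5PO (1.504 expected, adjusted permutation p = 0.716), and acid-base transport had BSG as 1 of 14 (0.702 expected, adjusted permutation p = 0.779). Ribosomal proteins had RPL3 as 1 of 40 (2.10 expected, adjusted permutation p = 1).

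Lists of other cell types served as a background. Muscle genes had TNNT1 as 1 of 25 (1.31 expected, adjusted permutation p = 0.932), and immune cell genes had CSF1R, CD19 and ITGAM as 3 of 24 (1.28 expected, adjusted permutation p = 0.252). Of the neuronal genes 0 of 25 were bound (1.05 expected), and of the hepatocyte genes 0 of 24 (1.19 expected), with an adjusted permutation p of 1 for each.

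Of 20 genes named before the data were examined, 8 were bound in the combined list: PDK1, LDHA, ANKRD37, BNIP3, SLC2A1, KDM3A, ADM and EGLN1. VEGFA had a peak in all 3 replicates without entering the combined list, whose nearest region lay 12582 bp from the gene (summed fold 59.5). NDRG1, a hypoxia-responsive gene, had peaks in replicates 1 and 2 (folds 4.69 and 9.42), and CYP1A1, the classic aryl hydrocarbon receptor target, also in replicates 1 and 2 (5.16 and 11.6). LEP, the leptin gene, had peaks in replicates 2 and 3 (10.2 and 16.3), both within 5 kb. PFKFB4 also had peaks within 5 kb of its ends in replicates 2 and 3 (7.12 and 6.47), beside the region inside the gene, 5907 bp from an end, that had folds of 28.5, 72.2 and 41.3 in the 3 replicates. TIPARP had a peak in replicate 2 (4.08). Within 5 kb of EGLN3, CA9, FLT1, GCM1, ERVW-1 and ERVFRD-1 no replicate had a peak. The nearest combined-list region lay 15996 bp from CA9 (27.8), 123683 bp from FLT1 (81.6), 180076 bp from EGLN3 (71.5) and 503094 bp from GCM1 (45.9), the trophoblast fusion regulator. Absence from a list says that no peak passed the authors' threshold at an unknown depth, not that ARNT was absent.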

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

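The tests of promoters open in any cell, of dense gene neighbourhoods and of a mislabelled library were chosen after the result was seen. Replicate 2 had 11 peaks and replicate 3 had 12 on contigs outside the assembled chromosomes, a signal in data that no comparison used. Replicate 1 had 2 such peaks, and folds ran from 1.31 on Un_KI270438v1 to 14.2 on 1_KI270713v1_random, both in replicate 2.

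The excess of bound hypoxia-induced and glycolysis genes (38 of 58 different genes, 2.77 expected) could in principle come from promoters that are open in any cell. Ribosomal and oxidative phosphorylation genes, which are active in nearly all cells, had 3 of 70 bound, below the 3.58 expected and the upper limit of 8 for matched lists. This count uses the combined list, which left out weaker regions, so it cannot decide on weaker signal at such promoters. A peak in any replicate was found at 13 of 40 ribosomal and 9 of 30 oxidative phosphorylation genes. The same held for 30 of 36 hypoxia-induced and 22 of 25 glycolysis genes. Among genes with a peak in any replicate, 77.6% of the hypoxia and glycolysis members were in the combined list. Of the others 19.7% were (one-sided Fisher exact test, p = 6.88e-18), so entry was not equal for any gene end with signal. The combined list kept the stronger regions, however (median summed fold 39.3 against 20.4 for those left out). Unequal entry was thus built in, and this test cannot exclude an artifact behind the excess. The bound count was 13.7 times the same expectation, which is matched on local gene density; the share of bound genes ran from 2.45% to 5.79% across the deciles of density, against 65.5% of these genes. No biological explanation was tested, since every library came from cells at 1% oxygen.

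Replicate 1 had fewer peaks than the others. A lower sensitivity of this library may account for that: where replicates 2 and 3 both had a peak, the replicate 2 fold was the higher one with probability 0.842 when replicate 1 also had a peak (median 14.9 against 7.33). An unrelated library is argued against by the 91.9% of replicate 1 peaks that overlapped a peak in both other lists. A mislabelled library of the same or a related target could overlap as well, so the overlap cannot decide on mislabelling. Whether read depth or the efficiency of the immunoprecipitation set the sensitivity stays open, since read totals are unknown. No biological explanation was tested.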

How the results depend on the processing

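The background of genes with a peak in any replicate, the lists without hypoxia-induced genes, the regions with a further authors' value of at most 0.05, gene bodies, summits and placement beside gene ends were chosen after the data were seen. The overlap of each replicate pair and the share of regions at gene ends (25.7% to 32.1% within 1 kb, 23.3% within 500 bp, 36.8% within 1 kb of an end of any annotated gene) stayed on the same side of their tests under all alternatives run. Regions in all 3 replicates numbered 657 with the strongest 1000 peaks of each list by −log10 q. In the pairs left when a replicate was dropped, shared regions numbered from 2431 (without replicate 2) to 5875 (without replicate 1). The share of the combined list found in the replicates ranged from 96.5% to 99.8% with a replicate left out, the highest without replicate 1. Bound genes numbered 2897 with regions of at least 2 replicates, 511 with the stronger 50% of the combined list, 88 with a further value of at most 0.05, 605 within 1 kb and 3394 within 50 kb. With a replicate left out, bound genes ranged from 1325 to 2829, the highest without replicate 1. These counts use regions found in both other replicates in place of the combined list, so they do not compare directly with its 975. The number of lists past the test, 9, fell to 3 against genes with a peak in any replicate and to 4 without hypoxia-induced genes. Both settings test fewer genes. The first also replaced the matched permutation test with a one-sided Fisher exact test, so the fall to 3 cannot be put down to the background alone. Under the other settings the number of lists past the test lay between 6 and 9. The cell cycle arrest list had 0 bound genes among regions with a further value of at most 0.05. Its 5 regions had further values from 0.244 to 0.916 and a median summed fold of 37.7, against 40.4 for all bound genes. Results for single lists and genes were counted once per alternative setting. Of these comparisons, 398 stayed on their side of the threshold, 23 moved past it, 38 fell short and 1 reversed. The lipid list passed in 2 of 15 settings, mitophagy in 7, the clock in 9, cell cycle arrest in 10 and collagen in 11. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, enter no test. The alternatives for the HIF core sequence, the motif panel and short sequences were not run, since no genome sequence was used here. Unknown depth limits what the absence of a peak shows.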

Other observations

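The tests restricted to regions away from gene ends and the test of strength against distance were chosen after the result was seen, as were the counts per chromosome. Aryl hydrocarbon receptor targets, with 0 of 12 bound within 5 kb, had 5 of 12 with a region within 50 kb that lay over 5 kb from every protein-coding gene end (0.756 expected, adjusted permutation p = 0.0036 over 24 lists). With all regions within 50 kb, the planned setting, the same 5 genes did not pass (1.78 expected, adjusted permutation p = 0.0681), and counting genes bound within 50 kb but not within 5 kb gave 0.0468. CYP1A1 and CYP1A2, neighbouring genes of xenobiotic metabolism, shared one such region (chr15:74763258-74763933, summed fold 84.3), 38068 bp and 6989 bp away. The others were SLC7A5, an amino acid transporter gene (chr16:87789644-87790481, 76.9), CYP1B1 (chr2:38096144-38096741, 62.5) and AHRR, which encodes a repressor of the receptor (chr5:402652-403478, inside the gene, 43.7). The same restriction gave 5 of 24 extravillous trophoblast genes (1.46 expected, adjusted permutation p = 0.0476), namely ITGA5 (68.9), FSTL3 (68.7), ITGB1 (47.3), ASCL2 (44.9) and ADAM12 (41.8), and 5 of 19 stress response genes (1.35 expected, adjusted permutation p = 0.0355), namely PPP1R15A (43.1), HERPUD1 (39.0), ATF4 (30.6), SESN2 (28.1) and ATF3 (27.2). Neither list passed with all regions within 50 kb (extravillous 7 of 24, adjusted permutation p = 0.121; stress response 7 of 19, 0.0960) or with genes bound within 50 kb but not within 5 kb (0.168 and 0.0600). Hypoxia-induced (9 of 36, adjusted permutation p = 0.0040) and glycolysis genes (6 of 25, 0.0348) also passed the restriction. Syncytiotrophoblast genes had 3 of 38 (2.72 expected, adjusted permutation p = 0.736), neuronal genes 0 of 25 (1.36 expected) and hepatocyte genes 0 of 24 (1.73 expected), the last 2 with an adjusted permutation p of 1.

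Cytotrophoblast and stem cell genes had 13 of 27 members with a combined-list region within 50 kb (4.18 expected, adjusted permutation p = 0.00080), a pattern picked because this list passed at that distance and not at 5 kb. The excess was smaller with regions of all 3 replicates (13 of 27, 5.21 expected, adjusted permutation p = 0.0030) and of at least 2 (16 of 27, 10.2 expected, adjusted permutation p = 0.0413). It may be distal binding at trophoblast genes; ITGA6 enters it through the region at PDK1, so the count was repeated with regions over 5 kb from every protein-coding gene end, which left 10 of 27 (permutation p = 0.0001, the smallest these permutations can give), namely KRT19, ARID3A, TFAP2C, FGFR2, ELF3, KRT8, KRT18, YAP1, TEAD4 and WNT7A. Wide flanks are argued against by lists matched on gene plus flanking space (3.81 expected, permutation p = 0.0001, likewise the smallest). Repeated use of regions is argued against by the 92.3% of bound genes that stand for distinct regions, KRT8 and KRT18 sharing one. The 17 regions near these genes, the one at PDK1 included, had a median summed fold of 52.0. Other regions within 50 kb of a gene had 39.6, so those near these genes were not the weaker. Both groups come from the combined list, which left out weaker regions, so the comparison cannot decide on weak signal at open elements. Signal at open elements, weak or strong, stays open, as no chromatin accessibility was used here, and no biological explanation was tested.

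Regions of all 3 replicates that the combined list kept had the higher summed fold with probability 0.965, and the ratio of the highest to the lowest of the 3 folds in the regions left out was 0.715 times that in the regions kept. The share of regions over 5 kb from a gene end was 55.0% in the strongest 25% and 57.6% in the weakest 25%, a difference of -2.65 percentage points (95% bootstrap interval -9.05 to 3.75), so the hypothesis that stronger regions lie farther from gene ends was not borne out.

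Chromosome X had 13 of 848 protein-coding genes bound (1.53%) against 4.87% of all genes (adjusted p = 4.65e-06, Fisher's exact test over chromosomes), and chromosome 16 had 7.73% (adjusted p = 0.00264, Fisher's exact test), the lowest adjusted values among 11 of 23 chromosomes past 0.05, of which 5 had a higher and 6 a lower share than all genes; neighbouring genes can share a region and are not independent. PGK1 was among the genes bound on chromosome X.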
